A study of Homo sapiens with 5 samples.

How the data were processed

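Human coronary artery endothelial cells, the cells that line the arteries supplying the heart muscle, were infected with Chlamydia (Chlamydophila) pneumoniae, a bacterium that grows inside human cells. RNA was profiled at 5 time points after infection on 5 single-channel Affymetrix arrays, 1 array per time point, with biotin-labelled cRNA made from total RNA, per the labels' protocols. The 5 min, 25 min and 2 h cultures formed the first infection set and were infected at about 80% confluence, while the 24 h and 60 h cultures formed the second and were infected at about 55% confluence and at a lower multiplicity of infection, per the labels' protocols. The growth protocol also names a starting time point, which was not analysed here, and no array of uninfected cells was used here. Each array was assigned to its time point from the labels. The first 3 time points are called the early arrays below and the last 2 the late arrays.

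The deposited values were intensity values, 1 per probe set and array, for 54675 probe sets on a linear scale. The submitters' processing notes name MAS5 without its role or version. The lowest value was 49.7, the highest 24674, and the 2% trimmed means of the 5 arrays differed by 1.62%, so the values had been brought to a common scale before they were deposited, and they were used as deposited. The lack of values near 0 is not the usual form of a MAS5 signal column, so the background correction and the way probes were combined into a probe set value are not given in the sources used here. A background left in the values would make every fold difference of a dim gene smaller than it was in the cells.

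Gene names came from the platform annotation, which listed 42898 of the probe sets with a gene. Of these, 41097 named 1 gene and 1801 named several. The other 11777 were unnamed here. The gene identifier of 41043 of the probe sets with 1 gene was found in a table of current RefSeq genes, used for names only, and 0 symbols changed. Probe sets with several genes, genes on the Y chromosome and XIST were left out, which left 19741 genes, 10511 of them with at least 2 probe sets. No coordinates were used.

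Values below the 40th percentile of all values pooled over the arrays, a signal of 134.4, were raised to that floor, and log2 was taken. A gene was represented by its probe set with the highest mean log2 signal. A gene with 1 side of a comparison at the floor has only a bound for its difference. Of the 19741 genes, 12961 lay above the floor on all 5 arrays and 3630 lay at or below it on all 5. Arrays have no read depth, and the number of arrays limits the precision.

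With 1 array per time point there is no spread between cultures to test against, so no p-value, SD or SE between time points is given. A gene was counted as higher or lower where its log2 difference was at least 1 (2-fold). Within the infection sets the comparisons were 25 min against 5 min, 2 h against 5 min, 2 h against 25 min, and 60 h against 24 h. For the late against the early arrays, a gene was counted only where both late values lay at least 1 log2 unit beyond all 3 early values, and the difference printed is the mean of the late minus the mean of the early log2 values. The only error that these arrays allow is the disagreement between probe sets of the same gene, given as a pooled SD per comparison from genes with at least 2 probe sets above the floor. It leaves out the spread between cultures, hybridisations and days.

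Before the data were examined, 26 gene lists were fixed. They cover inflammatory, interferon, antigen presentation, sensing, endothelial, arterial, proliferation, metabolic and stress genes, and markers of smooth muscle, leukocytes and epithelium. For each list and comparison the median log2 difference was set against 10000 random lists of the same size matched on mean signal in 10 bins. This describes the arrays at hand and is not a test. Of the 130 medians, 6.5 would lie outside the 95% range of random lists if genes varied independently of each other. Genes of a list can vary together, the comparisons share arrays and some lists share genes, so more can lie outside without an effect of infection.

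The genes named were also chosen by a rule fixed before the data were examined. For each comparison it took the 10 genes with the largest differences in each direction, among genes above the floor on every array compared, with a difference of at least 1 log2 unit and probe sets above the floor that all pointed the same way. It added up to 6 members of each list with a difference of at least 1 log2 unit, and 18 genes to be reported whatever their values, of which 17 were measured. The text names a part of these.

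The rule was tested on simulated arrays that held the real mean signals, noise of the size of the probe set disagreement, and 200 genes changed by known amounts. For 2 h against 5 min, 18 of 50 genes changed 2-fold, 40 of 50 changed 3-fold and 40 of 50 changed 4-fold were called, with 0 of 19541 unchanged genes called. Among the genes changed 4-fold, 28 of 28 raised and 12 of 22 lowered were called. For the late against the early arrays 1 of 50 genes changed 2-fold, 36 of 50 changed 3-fold and 40 of 50 changed 4-fold were called. For 60 h against 24 h, 8 of 19541 unchanged genes were called. In the simulation the rule therefore missed lowered genes more often than raised ones. The simulated noise was normal and left out the spread between cultures, hybridisations and days. The 0 of 19541 is therefore no measure of false calls between real cultures. All probe sets of a changed gene moved by the same amount. Probe sets that jump alone on an array or disagree about a change were not simulated. The calls among unchanged genes and the shares recovered may therefore differ on the real arrays.

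Alternatives tried were quantile normalisation, scaling to a common median, floors at the 20th and 60th percentile, no floor with 16 added before log2, the mean over all probe sets of a gene, only probe sets of the plain type, the median difference over probe sets, limits of 1.5-fold and 3-fold, only genes with at least 2 probe sets that all passed, random lists without matching, and leaving out each array in turn for the late against the early arrays. List medians for the late against the early arrays without the 25 min array, and the counts at 2 h without a group of genes described with them, were added after seeing the data. The result of 1 gene at 25 min against 5 min is not reported here, and the counts include that gene. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.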

Results

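Infected coronary artery endothelial cells were profiled at 5 min, 25 min and 2 h (early arrays, first infection set) and at 24 h and 60 h (late arrays, second infection set), with 1 array at each time. No time point had a replicate, so no difference below has a check against the spread between cultures. The 2% trimmed mean signal of the arrays ran from 337 to 342. Across probe sets, the log2 signals of the early arrays correlated with each other at 0.986 to 0.991, those of the 24 h and 60 h arrays at 0.967, and early with late arrays at 0.965 to 0.975. Markers of endothelium were bright on all 5 arrays. PECAM1, an adhesion molecule of endothelial junctions, had signals of 5407 to 7689, CDH5, the cadherin of those junctions, 6886 to 8276, and VWF, a clotting protein stored in endothelial cells, 1767 to 2428. Of 14 markers measured in the leukocyte list, 6 lay at or below the floor on all 5 arrays, among them PTPRC (CD45), the pan-leukocyte surface phosphatase. The list also holds HBB, a marker of red cells, and PPBP and PF4, markers of platelets. The ratio of 3' to 5' ACTB signal, which increases when RNA is degraded, was 1.39, 1.62, 1.35, 1.16 and 1.41 in order of time, and that of GAPDH 1.04, 1.09, 1.04, 1.05 and 1.05.

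**Figure D1:**
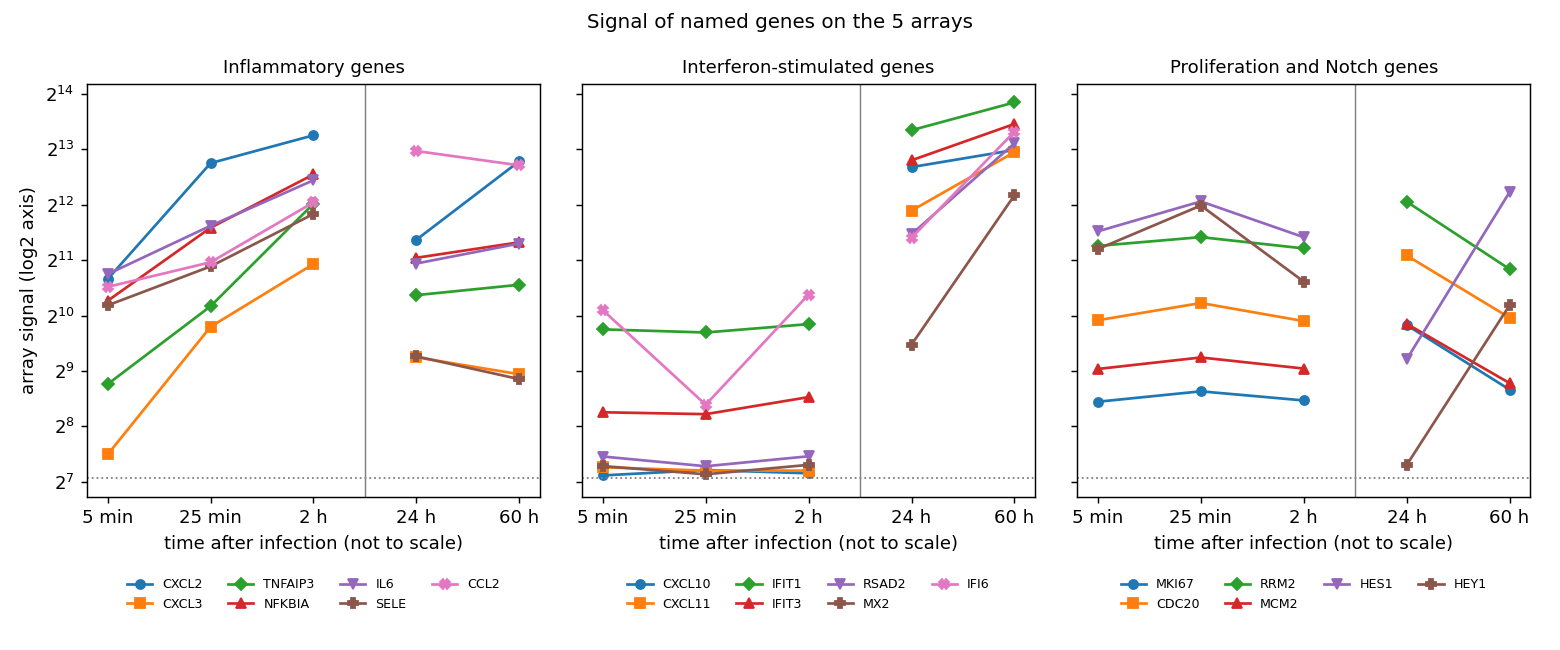
Array signal on a log2 axis against time after infection, with the times evenly spaced and not to scale, for inflammatory genes (left), interferon-stimulated genes (centre) and proliferation and Notch genes (right). Each point is 1 array, the vertical line separates the 2 infection sets and the dotted line is the floor of 134.4; CXCL10 lay at 139 to 148 on the early arrays and at 6560 and 8133 on the late arrays, and TNFAIP3 was highest at 2 h, at 4150.

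The first comparison asked which transcripts differed at 25 min from 5 min after infection. Transcripts of inflammatory signalling were among the genes that were higher. CXCL3 and CXCL2, chemokines that attract neutrophils, were 4.94-fold and 4.27-fold higher at 25 min (log2 differences of 2.30 and 2.09, the latter 0.88 on another probe set), and the related CXCL1 was 2.19-fold higher (1.13). TNFAIP3 (A20) and NFKBIA (IκBα), inhibitors of NF-κB signalling that NF-κB itself induces, were higher by 1.41 and 1.32, and ZFP36, a protein that promotes decay of inflammatory mRNAs, by 1.59. EFNA1, an ephrin ligand that inflammatory cytokines induce in endothelium, was higher by 1.25. In all, 14 genes were at least 2-fold higher, 7 of them in a fixed list, and 26 at least 2-fold lower.

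Immediate early genes, which are switched on without new protein synthesis, were higher as a group at 25 min. Of 31 measured, 28 lay above 0 with a median of 0.51, against a 95% range of -0.03 to 0.12 for random lists, although only ZFP36 and ATF3, a stress-induced transcription factor (1.01, and 0.74 and 0.15 on its other probe sets), passed 2-fold. EGR1 and FOS, transcription factors of this group, stood at 0.77 and 0.58, and EGR1 at 1.79 and 0.57 on its other probe sets. The NF-κB feedback and survival list had a median of 0.23 with 2 of 20 members past 2-fold (range -0.02 to 0.16), the cytokine and chemokine list 0.15 with 3 of 29 (0.00 to 0.13), and the arterial and Notch list 0.25 with 0 of 18 (-0.03 to 0.17). With the mean of all probe sets each of these medians fell inside its range, at 0.15, 0.13 and 0.14. The adhesion molecules and cytokines followed by name stayed below 2-fold at 25 min, with SELE (E-selectin) at 0.70, ICAM1 at 0.81, VCAM1 at 0.29, IL6 at 0.87, CXCL8 (interleukin 8) at 0.53, CCL2 at 0.44 and F3 (tissue factor) at 0.41. PECAM1, CDH5 and VWF stood at 0.00, 0.00 and 0.33, and MKI67, a marker of dividing cells, at 0.19.

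Genes lower at 25 min included IFI6, an interferon-stimulated mitochondrial protein (-1.71), PSENEN, a subunit of γ-secretase (-1.58), NR1D2, a nuclear receptor of the circadian clock (-1.34), MALAT1, a long nuclear RNA (-1.35, and from -3.29 to -0.02 over its other probe sets), and SCN2B, a sodium channel subunit (-2.88), which had a signal of 1013 at 5 min and of at most 166 on the other arrays. The interferon-stimulated list had a median of -0.09 with 1 of 32 members 2-fold lower (range -0.03 to 0.13). Of the 26 lower genes, 10 were 2-fold below all 4 other arrays on the 25 min array, which also had the highest ACTB and GAPDH 3' to 5' ratios. Differences between probe sets of the same gene had a pooled SD of 0.23 log2 units. The probe sets of a gene often disagreed: NFKBIA stood at 0.21 and NR1D2 at -0.00 on their other probe sets. With the mean of all probe sets, those at the floor included, 9 genes were higher and 4 lower.

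At 2 h several of the same inflammatory genes stood further above their 5 min level, while CXCL1 (1.07) and ZFP36 (1.43) stood slightly below their 25 min difference. CXCL3 was 10.8-fold higher (log2 difference 3.44), TNFAIP3 9.56-fold (3.26, and 3.54 on its other probe set), and NFKBIZ, a nuclear IκB protein needed for secondary NF-κB targets such as IL6, 7.59-fold (2.93, and 2.72 on the other). CXCL2 was higher by 2.60 and NFKBIA by 2.28 (0.26 on its other probe set, which was dim). Among cytokines, IL6 was higher by 1.70, CCL2, which attracts monocytes, by 1.53, LIF, a cytokine of the IL6 family, by 1.44, and IL1A by 1.34. SELE, which slows rolling leukocytes on activated endothelium, was higher by 1.65, and ICAM1, which leukocytes bind firmly, by 1.00 (0.85 and 0.59 on its other probe sets).

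By list, 8 of 29 cytokines and chemokines were at least 2-fold higher at 2 h than at 5 min (median 0.10, range of random lists -0.04 to 0.05), 5 of 20 NF-κB feedback and survival genes (0.18, -0.07 to 0.05), 4 of 31 immediate early genes (0.41, -0.06 to 0.03) and 2 of 13 adhesion molecules (0.02, -0.07 to 0.03), with no member of these lists 2-fold lower. The NF-κB list included IRF1, a transcription factor of the interferon response (1.57, and 0.94 on its other probe set), and BCL2A1, an inhibitor of apoptosis (1.29). The immediate early list included ATF3 (1.45, and 1.20 and 0.36 on its other probe sets), ZFP36 (1.43), JUNB (1.06) and GADD45B (1.05). PMAIP1 (NOXA), which promotes apoptosis, was higher by 1.20. CXCL8 stood at 0.86, but at 1.44 on its other probe set, which was also bright. F3, which starts coagulation, stood at 0.83, FOS at 0.39, EGR1 at -0.05 and VCAM1 at -0.18. The interferon-stimulated list had a median of 0.07 with 0 of 32 past 2-fold (range -0.07 to 0.02), and IFIT1 stood at 0.10. Cholesterol synthesis and uptake genes had a median of -0.13 with 0 of 17 past 2-fold (-0.09 to 0.04), and genes of the YAP list, which respond to cell contact, 0.13 with 0 of 16 (-0.08 to 0.05). The cholesterol median was -0.07 with the mean of all probe sets, inside its range. PECAM1, CDH5, VWF and MKI67 stood at 0.08, -0.13, 0.27 and 0.02.

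In total 55 genes were at least 2-fold higher at 2 h than at 5 min and 2 were lower, DEPP1 (-1.33, and -0.46 on its other probe set), which FOXO factors induce, and SCN2B. The pooled SD between probe sets was 0.16. Of the 55, 24 lay outside the fixed lists and were 2-fold above all 4 other arrays on the 2 h array, and 31 remained without them. They included IQCB1 (5.17, against 0.04 on its other probe set) and KCNQ3 (4.04, against 0.14 on each of its others). Where such genes had another probe set above the floor on at least 1 array, 0 of 12 had one at least 0.5 log2 units above the other arrays. With the requirement that all of at least 2 probe sets, those at the floor included, pass 2-fold, 5 genes were higher.

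Between 25 min and 2 h, NF-κB regulators and cytokines made up most of the list members that differed by 2-fold. NFKBIZ was higher at 2 h by 2.07 (1.00 on its other probe set), TNFAIP3 by 1.85, LIF by 1.38, CXCL3 by 1.13, CCL2 by 1.08 and IL1A by 1.02. SELE (0.95), NFKBIA (0.96), IL6 (0.82), CXCL8 (0.33, and 0.87 on its other probe set) and ICAM1 (0.20) did not reach 2-fold. EGR1 stood at -0.81 (-1.73 and -0.67 on its other probe sets) and FOS at -0.18. Of the immediate early list 0 of 31 members passed 2-fold (median 0.03, range -0.13 to 0.02), and 2 of 20 NF-κB genes and 4 of 29 cytokines and chemokines were higher (medians 0.05 and 0.00, ranges -0.16 to 0.02 and -0.12 to 0.00). HEY1, a transcriptional repressor induced by Notch, was lower at 2 h (-1.37, and -1.45 on its other probe set), and the arterial and Notch list had a median of -0.24 with 1 of 18 members 2-fold lower (-0.18 to 0.03).

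Across the genome, 57 genes were higher at 2 h than at 25 min and 3 were lower, HEY1, DEPP1 (-1.29, and -0.19 on its other probe set) and EIF5A, a translation factor that was named after its value was seen. The pooled SD between probe sets was 0.26. Of the 57, 10 were the genes 2-fold below all other arrays on the 25 min array, such as IFI6 (1.99) and PSENEN (1.48), and 24 were those outside the lists raised on the 2 h array alone, without which 33 remained. With the mean of all probe sets 28 were higher.

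The late arrays were compared with the early ones to ask what distinguished cells a day or more after infection. Genes that interferon induces were far higher on both late arrays. CXCL10 and CXCL11, chemokines that attract activated T cells, were 51.1-fold and 36.7-fold higher (log2 differences of 5.67 and 5.20). Their early signals of 139 to 148 and 147 to 154 lay near the floor, so these folds are better read as lower bounds. RSAD2 (viperin), an antiviral enzyme, was higher by 4.89, IFIT3, IFIT2 and IFIT1, which bind foreign RNA or act with proteins that do, by 4.80, 4.63 and 3.83, OASL by 4.06, and IFITM1, a membrane protein that restricts viral entry, by 4.20. The early signals of RSAD2 (156 to 176) and OASL (170 to 186) also lay near the floor, so their differences may be too small. TNFSF10 (TRAIL), a ligand that can trigger apoptosis, was higher by 3.91, and CCL5, a chemokine for T cells and monocytes, by 2.91 (2.25 and 1.91 on its other probe sets), also from early signals near the floor or below it.

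Of 32 interferon-stimulated genes measured, 28 were at least 2-fold above all early arrays on both late arrays and none was lower, with a median of 2.75 against -0.14 to 0.08 for random lists. Against the mean of the early arrays their median was 1.98 at 24 h and 3.38 at 60 h. The 4 that did not pass were IFI27, IRF9, GBP2 and BST2, named after their values were seen. In the antigen presentation list, 4 of 18 passed and all 18 lay above 0 (median 0.90, range -0.17 to 0.10): PSMB9 (2.46) and PSMB8 (1.36), subunits of the immunoproteasome, TAP1, the peptide transporter (2.04), and NLRC5, the transcriptional activator of MHC class I genes (1.72). Of 25 bacterial sensing genes 2 passed, TLR3, a receptor for double-stranded RNA (2.77), and CASP1, the protease that matures interleukin 1β (2.31), with a list median of 0.07 (-0.07 to 0.08). SOD2, a mitochondrial superoxide dismutase, was higher by 1.82, CX3CL1 (fractalkine) by 1.58, CLDN5, a claudin of endothelial tight junctions, by 1.69, and DLL1, a Notch ligand, by 1.63 (-0.05 on its other probe set). CX3CL1 and DLL1 had early signals near the floor, at 148 to 165 and 152 to 190.

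Most inflammatory genes named at 2 h differed by less than 2-fold in mean between late and early arrays. TNFAIP3 stood at 0.15, NFKBIA at -0.28, CXCL8 at -0.38, IL6 at -0.48, ATF3 at -0.28, ICAM1 at 0.29, F3 at -0.51 and VCAM1 at -0.41. The early mean holds the 25 min and 2 h values, so a difference near 0 need not mean a return to the 5 min level. TNFAIP3 had a signal of 434 at 5 min and of 1322 and 1506 late, and NFKBIA 1232 against 2110 and 2561. F3 went the other way, with 251 against 228 and 240, as did VCAM1, with 1941 against 1508 and 1493. In mean, CCL2, IRF1, SELE and GADD45B differed more, with late values that did not overlap the early ones, but missed the 2-fold gap. CCL2, at 1466 to 4220 on the early and 8021 and 6706 on the late arrays, had a mean difference of 1.67 and a gap of 0.67, and IRF1 had 1.69 and a gap of 0.64. SELE ran from 1164 to 3649 early and was 615 and 462 late, a mean difference of -1.91 with a gap of -0.92, and GADD45B had -1.32 with a gap of -0.58. Of 29 cytokines and chemokines 5 passed as higher (median 0.13, range -0.08 to 0.08), of 20 NF-κB genes 1 did (0.02, -0.13 to 0.09), and of 13 adhesion molecules 0 did (-0.09, -0.16 to 0.09).

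Few list members were lower on both late arrays. EGR1 was lower by a log2 difference of -1.81 (-1.20 and -0.97 on its other probe sets) and NR4A2, an orphan nuclear receptor, by at least -2.53, the 2 of 31 immediate early genes that passed (median -0.50, range -0.12 to 0.07). Against the mean of the early arrays, the immediate early list had a median of -0.26 at 5 min, -0.62 at 24 h and -0.36 at 60 h. ID2, an inhibitor of helix-loop-helix factors that BMPs induce, stood at -2.22 and TGFB2, the growth factor TGF-β2, at -1.94 (0.34 on 1 of its other probe sets), the 2 of 28 extracellular matrix and TGF-β genes that passed (median -0.36, -0.14 to 0.08). POSTN (periostin), a matrix protein, stood at -1.93 and BMP2 at -1.50 (-0.95 on its other probe set). YAP-list genes had a median of -0.34 with 0 of 16 past 2-fold (-0.17 to 0.11), cholesterol genes -0.26 with 0 of 17 (-0.18 to 0.12), and arterial and Notch genes -0.21 with 1 of 18 higher (-0.15 to 0.11). Mitosis genes had a median of 0.46 (-0.14 to 0.08) and replication genes of 0.18 (-0.13 to 0.08), with none of 30 or 29 past 2-fold, and MKI67 stood at 0.73.

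Most markers of cell type differed by less than 2-fold between early and late arrays. PECAM1, CDH5 and VWF stood at 0.25, -0.10 and -0.14, and the endothelial identity list at 0.081 (range -0.134 to 0.076) with 1 of 27 members, CLDN5, past 2-fold. That list median lay just above its range, but inside it with quantile normalisation (0.075) and the median difference over probe sets (0.071). The leukocyte list had a median of 0.00 with 0 of 14 past 2-fold, the epithelial list 0.00 with 0 of 11, and the smooth muscle and fibroblast list -0.00 with 1 of 19 lower, POSTN. Medians of the other lists were -0.14 for coagulation, -0.03 for hypoxia and glycolysis, 0.12 for unfolded protein and amino acid responses (range -0.14 to 0.09), 0.09 for heat shock, 0.11 for oxidative stress (-0.17 to 0.10), -0.04 for p53 targets, -0.06 for ribosomal proteins, 0.03 for oxidative phosphorylation and 0.34 for 7 histone genes (-0.21 to 0.18), with no member of any past 2-fold. With plain probe sets the unfolded protein median was 0.01 and the oxidative stress median 0.08, both inside their ranges. The medians of these cell type and other lists lay inside their ranges where none is given.

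In all 95 genes were higher and 24 lower on the late arrays, and 42 and 5 of these belonged to a fixed list. With the mean of all probe sets 9 were lower, and 22 higher and 3 lower genes had at least 2 probe sets that all passed. The pooled SD between probe sets was 0.21. Time, confluence and multiplicity of infection changed together between early and late arrays and cannot be told apart. Without the 24 h array 216 genes were higher and 74 lower, and the lower count was 40 without the 5 min array and 82 without the 60 h array.

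Between 24 h and 60 h, within the second infection set, interferon-stimulated and antigen presentation genes were higher at the later time. MX2, a dynamin-like antiviral GTPase, was 6.48-fold higher (log2 difference 2.70), IFITM1 5.32-fold (2.41), ISG20, an antiviral exonuclease, 4.17-fold (2.06), IFI6 3.77-fold (1.91) and IFI44L 3.60-fold (1.85). Of 32 interferon-stimulated genes, 17 were at least 2-fold higher and none lower (median 1.06, range of random lists -0.23 to 0.11), while IFIT1 stood at 0.50. Of 18 antigen presentation genes, 7 were higher and none lower (0.92, -0.25 to 0.18), among them PSMB9 (1.76) and the class I heavy chains HLA-C (1.48), HLA-B (1.44) and HLA-F (1.44), whose near-identical sequences can share probes. CTSS (cathepsin S), a protease of antigen processing, was higher by 2.18 and CASP1 by 1.26.

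Notch targets were among the largest differences between 24 h and 60 h. HES1 and HEY1, transcriptional repressors induced by Notch, were 8.11-fold and 7.38-fold higher at 60 h (3.02 and 2.88), and SOX17, an arterial transcription factor, was higher by 1.29, whereas GJA4 (connexin 37), an arterial gap junction protein, was lower (-1.58). The arterial and Notch list as a whole had a median of 0.01 with 3 of 18 higher and 1 lower (range -0.24 to 0.21). HES1 had a signal of 592 and HEY1 of 158 at 24 h, below the 2729 to 4271 and 1566 to 4057 of the early arrays. Immediate early genes had a median of 0.46 with 3 of 31 higher and 1 lower (-0.18 to 0.14), and FOS was the lower one (-2.11). DDIT3 (CHOP) and DNAJB9, induced by endoplasmic reticulum stress, were higher by 1.27 and 1.38, the 2 of 25 members of the unfolded protein list past 2-fold (median 0.04, -0.23 to 0.17), and IL33, a nuclear cytokine of endothelium, was higher by 1.17. Core and linker histone genes had a median of 0.63 with 1 of 7 higher (-0.33 to 0.32), H2BC5 (1.34). Medians above the range of random lists were also seen for cytokines and chemokines (0.26, 5 of 29 higher), YAP-list genes (0.27, 0 of 16), bacterial sensing genes (0.25, 2 of 25) and p53 targets (0.24, 1 of 18). Of these, cytokines and chemokines (0.03) and p53 targets (0.08) fell inside their ranges with plain probe sets, and YAP-list genes (0.16) with the median difference.

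Genes of proliferation were lower at 60 h than at 24 h. Of 30 mitosis genes 29 lay below 0, with a median of -0.65 (range -0.24 to 0.12), and 2 passed 2-fold, MKI67 (-1.16, and from -0.90 to -0.48 on its other probe sets) and CDC20, an activator of the anaphase-promoting complex (-1.12). Of 29 replication genes 5 were 2-fold lower and none higher (-0.60, -0.22 to 0.14), among them RRM2, a subunit of ribonucleotide reductase (-1.22, and -0.65 on its other probe set), UHRF1, which maintains DNA methylation (-1.16), and MCM2, a part of the replicative helicase (-1.07). GINS2, of the same list, stood at -1.07 and at 0.64 on another probe set. Against the mean of the early arrays, mitosis genes had a median of 0.71 at 24 h and 0.08 at 60 h, and replication genes 0.52 and -0.12. Also lower at 60 h were SOCS1, a feedback inhibitor of interferon signalling (-1.66, but -0.18 and -0.09 on its other probe sets above the floor), HMOX1, the haem oxygenase induced by oxidative stress (-1.60), SELP (P-selectin, -1.05), KRT18, a keratin of simple epithelia (-1.35), BCL2A1 (-1.16), and ACO1, an aconitase that binds iron-responsive mRNAs (-2.48).

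Other genes higher at 60 h than at 24 h were CXCL2 (1.42), ZFP36 (1.10), CXCL11 (1.05) and CCL5 (1.06). Below 2-fold stood PECAM1 at 0.47, CDH5 at 0.24, VWF at -0.37, SELE at -0.41, ICAM1 at 0.70, VCAM1 at -0.01, CCL2 at -0.26, CXCL8 at 0.48, IL6 at 0.36, F3 at 0.07, EGR1 at 0.53, ATF3 at -0.13, NFKBIA at 0.28 and TNFAIP3 at 0.19. The leukocyte list had a median of 0.03 with 0 of 14 past 2-fold and the epithelial list of 0.00 with 1 of 11 lower. The ACTB 3' to 5' ratio was 1.16 at 24 h and 1.41 at 60 h. In all 262 genes were higher and 98 lower at 60 h, the largest counts of the comparisons within an infection set. The pooled SD between probe sets was also the largest, at 0.31. With the mean of all probe sets 125 were higher and 48 lower, and 18 and 3 genes had at least 2 probe sets that all passed. Over the 5 comparisons, 43 of the 130 list medians lay outside the 95% range of random lists, against 6.5 if genes varied independently. That number is too low where genes of a list vary together, so the excess is not a test. Of the 43, 20 fell inside that range under at least 1 alternative, all with a median below 0.4 in size, among them cytokines and chemokines in 4 comparisons and arterial and Notch genes in 3.

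**Figure D2:**
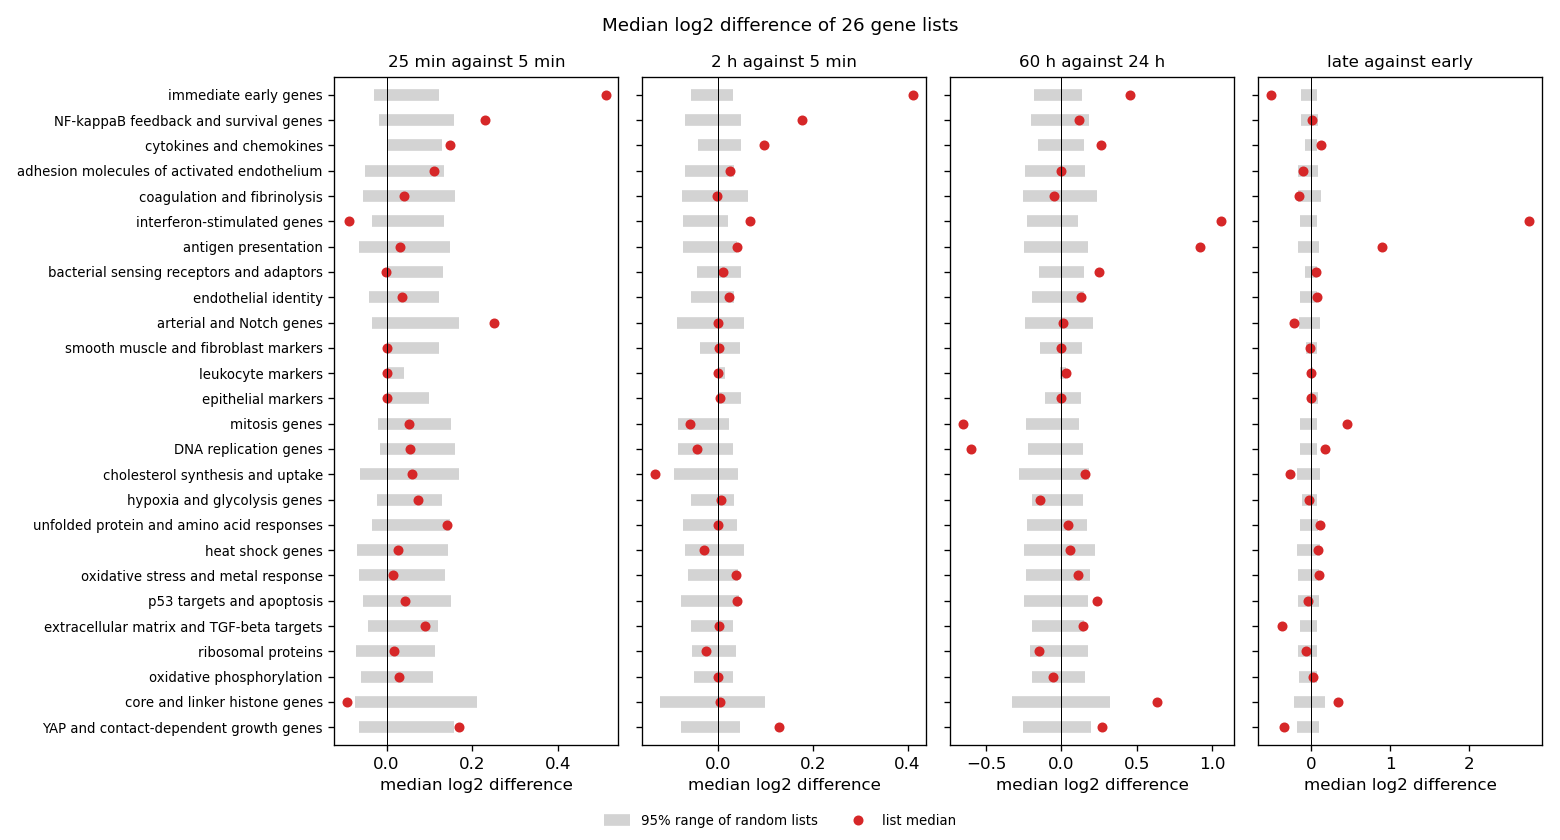
Median log2 difference (horizontal axis, a scale of its own in each panel) of each of 26 gene lists in 4 comparisons, with red points for list medians and grey bars for the 95% range of 10000 random lists matched on signal. Interferon-stimulated genes lie far right of their bar in the late comparisons (2.75 for late against early, 1.06 for 60 h against 24 h), and mitosis genes lie left of theirs at 60 h against 24 h (-0.65).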

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

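The counts without the genes raised on the 2 h array alone, the list medians without the 25 min array, and the choice to give in full the lists with a median of at least 0.4 in size were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each time point has 1 array and no result comes from a test. Quantile normalisation, scaling to a common median, other floors and no floor kept all 10 gene counts within 1.5 times, and no scaling moved the median of all genes by over 0.1. The choice of probe set mattered more. Part of this was built in, since a probe set at the floor on all arrays entered the mean and the median difference as 0. Such a probe set also failed where all had to pass. How much of the change came from this, and how much from disagreement between probe sets above the floor, was not tested. Arrays have no depth; signal over background limits the genes near the floor, and fold sizes depend on a background step that is not known.

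Counts are given as higher and lower where both moved. With the mean of all probe sets they were 9 and 4 for 25 min against 5 min, 0 lower for 2 h against 5 min, 28 higher for 2 h against 25 min, 125 and 48 for 60 h against 24 h, and 9 lower for late against early. With the median difference over probe sets they were 8 and 10, 34 and 0, 27 higher, 127 and 52, and 9 lower, in the same order. With only plain probe sets they were 36 and 1 for 2 h against 5 min and 149 higher for 60 h against 24 h. At 1.5-fold they were 94 and 102, 116 and 22, 173 and 124, 1322 and 805, and 178 and 114 in the order of the 5 comparisons, and at 3-fold 5 and 3, 23 and 1, 22 and 0, 36 and 12, and 42 and 4, as a lower or higher limit makes them. Where all of at least 2 probe sets had to pass, they were 1 and 0, 5 and 0, 2 and 1, 18 and 3, and 22 and 3, over fewer genes. Without genes outside the lists raised on the 2 h array alone, 31 were higher for 2 h against 5 min and 33 for 2 h against 25 min. For late against early, the counts were 216 and 74 without the 24 h array, 82 lower without the 60 h array and 40 lower without the 5 min array.

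No list median of at least 0.4 in size changed sign. Of the alternatives for the 31 smaller medians outside their random range, 199 values stayed within the SD of random lists, 58 moved beyond it, 54 of them towards 0, and 1 changed sign. Of the 43 medians outside their random range, 20 fell inside it under at least 1 alternative, with the range kept as in the main setting, a comparison added after seeing the data. Cytokines and chemokines went from 0.15 to 0.00 (floor at the 60th percentile) and 0.02 (plain) at 25 min against 5 min, from 0.10 to 0.00 (60th percentile), 0.04 (mean) and 0.03 (median difference) at 2 h against 5 min, from 0.26 to 0.15 (60th percentile) and 0.03 (plain) at 60 h against 24 h, and from 0.13 to 0.01 (60th percentile) and 0.00 (plain) for late against early, where it was 0.20 without the 25 min array. Arterial and Notch genes went from 0.25 to 0.14 (mean) and 0.13 (median difference) at 25 min against 5 min, from -0.24 to -0.10 (mean) at 2 h against 25 min, and from -0.21 to -0.11 (plain) and -0.13 (without the 25 min array) for late against early. With the median difference, the NF-κB list at 25 min against 5 min went from 0.23 to 0.13 and cholesterol genes for late against early from -0.26 to -0.12. Extracellular matrix and TGF-β genes for late against early stayed outside, at -0.21 with the mean and -0.21 with the median difference, against -0.36. Immediate early genes at 25 min against 5 min had medians of 0.30 (mean of all probe sets), 0.39 (plain probe sets) and 0.38 (median difference), at 2 h against 5 min 0.39 (plain), at 60 h against 24 h 0.35 (mean) and 0.35 (plain), and for late against early -0.45 (mean), -0.26 (plain) and -0.44 (without the 25 min array). Interferon-stimulated genes at 60 h against 24 h had 0.85 (mean) and 0.88 (median difference), and for late against early 2.70 (no floor), 2.36 (mean), 2.61 (median difference) and 2.66 (without the 25 min array). Antigen presentation genes had 0.64 (mean), 0.62 (plain) and 0.67 (median difference) at 60 h against 24 h and 0.75 (plain) for late against early. Mitosis genes had -0.49 (mean), -0.43 (plain) and -0.49 (median difference) at 60 h against 24 h, and 0.37, 0.37 and 0.36 for late against early. Histone genes at 60 h against 24 h had 0.40 (plain). With plain probe sets, 4 results changed sign: the bacterial sensing list at 25 min against 5 min (0.0023) and, at 60 h against 24 h, NR4A1 (-0.15), ERAP1 (-0.16) and GINS2 (0.64). Of the alternatives for named genes, 1008 values stayed within the probe set SD and 163 moved beyond it, and all 43 list percentiles kept their side with unmatched random lists.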

Other observations

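The genes in this paragraph and the next were chosen after their values were seen. IDO1, which breaks down tryptophan and can starve intracellular chlamydiae of it, lay at or below the floor of 134.4 on the 3 early arrays and had signals of 1211 at 24 h and 1581 at 60 h, a difference of at least 3.36 log2 units. BATF2, an interferon-induced transcription factor, likewise went from the floor to 821 and 1026. IFNB1, the gene of interferon β, was above the floor on the 24 h array alone, at 463. This rests on 1 array. Among genes 2-fold higher on that array alone, another probe set also rose in only 1 of 5 that had one above the floor. SOCS1, a feedback inhibitor of interferon signalling, was also highest at 24 h, with 545 against 134 to 148 on the early arrays and 172 at 60 h, but only on 1 probe set. Its others above the floor had 161 and 187 at 24 h, against 142 and 176 at 60 h. The complement genes C1S, C1R and CFB were highest at 60 h, at 740, 389 and 711, against 190, 148 and 238 at 24 h. LAMP3, a lysosomal membrane protein, followed the same order with 1221 at 60 h and 369 at 24 h.

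Between late and early arrays INHBA, a subunit of activin, differed by -1.28, TGFBR1, a TGF-β receptor, by -1.19, and CITED2, a transcriptional co-regulator, by -1.48. TXNIP, a thioredoxin inhibitor that glucose induces, was higher by 2.09. Setting any 2 arrays against the other 3 gives 10 splits. The late arrays against the early ones gave 119 genes past the rule, and the highest other split gave 2. Of 12961 genes above the floor on all arrays, 4246 (32.8%) had late and early values that did not overlap. Averaged over the 10 splits this share is 20% where values do not tie. The share of each other split was not computed and genes vary together, so the excess over 20% cannot be judged.

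Apart from the rescaling of the arrays, which had been chosen beforehand, the tests in the rest of this part were chosen after the results were seen. So were the limits of 25%, 50% and 0.5 log2 units and the restriction to genes outside the lists. The first pattern is the 24 genes outside the lists that were 2-fold above every other array on the 2 h array, among them IQCB1 and KCNQ3. A change of the whole transcript at 2 h should move other probe sets of the gene, and 0 of 12 genes with another probe set above the floor had one that also lay 0.5 log2 units above the other arrays. The probe set used for a gene had the highest mean over all arrays, the 2 h array included. A probe set high at 2 h alone was thus more likely to be used, and part of this disagreement was built in by that choice. Over all genes high on that array alone the count was 2 of 14, and for genes high on the 60 h array alone it was 28 of 41, or 10 of 22 outside the lists, so the test could have come out otherwise. For genes high on the 24 h array alone it was 1 of 5, or 0 of 4 outside the lists, so low agreement was not particular to the 2 h array. A fault of single probe sets on that array may account for these genes and predicts the same 0 of 12. What such a fault would be was not tested, and cross-hybridisation to another RNA could not be checked. A transcript form that only 1 probe set reads was not tested.

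The second pattern is the 10 genes that were 2-fold below every other array on the 25 min array, including IFI6, PSENEN and NR1D2. A fall of the whole transcript was borne out by another probe set in 1 of 8 genes that had one above the floor. Above the floor here means on at least 1 array. The other probe set of FOLR1 lay below the floor on the early arrays (117, 117 and 116), so it could not fall. The count argues against a fall of the whole transcript for most of the 8 genes. Over all genes low on a late array alone, the count was 7 of 13 at 24 h and 7 of 10 at 60 h. Outside the lists it was 1 of 8 at 25 min, 1 of 7 at 24 h and 6 of 9 at 60 h. Agreement was thus lower at 25 min than on the late arrays over all genes, but outside the lists it was similarly low at 24 h. Lower RNA integrity of that sample may contribute, since the ACTB 3' to 5' ratio was 1.62 there and at most 1.41 elsewhere. Signals of the platform's spike-in control probe sets were also lowest there, at -0.25 (hybridisation) and -0.62 (poly-A) log2 units against the 5 min array. The 2 h, 24 h and 60 h arrays stood at -0.15 to -0.10 and -0.45 to -0.38, so the 5 min array was highest in both. RNA integrity was thus not the only measure that set the 25 min array apart. The ratios of 1 sample cannot show that the integrity lowered these genes in particular. IFI6 and PSENEN have a single probe set each, so a short-lived fall of either stays open.

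The third pattern is the higher level of interferon-stimulated genes on the late arrays. Leukocytes in the late cultures would bring their own abundant transcripts, but 0 of 14 markers in the leukocyte list were 2-fold higher on a late array. The largest excess was 0.53 log2 units (ITGAX), and PTPRC, LYZ and 4 others, PPBP among them, lay at or below the floor on all arrays. HBB, PPBP and PF4 in this list mark red cells or platelets and do not bear on leukocytes. Rescaling changed the median of the interferon-stimulated list little, to 2.72 under the scaling that lowered it most, against 2.75 as given. The trimmed means of the arrays differed by only 1.62% before rescaling, so this check could hardly have come out otherwise. The lower confluence and multiplicity of infection of the second set cannot be told apart from time for the median of 2.75, but a fixed offset of that set would cancel in the further difference of 1.06 between 60 h and 24 h, where both arrays come from it. A response to infection that builds up with time is a hypothesis that may fit both; without an uninfected culture of the same age, time in culture stays open.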
